A study of Mus musculus with 12 samples.

How the data were processed

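RNA was measured in 12 libraries of mouse small intestinal organoids, 6 from Young and 6 from Aged mice of the C57BL/6JRj strain. Per the labels' protocols, poly(A) RNA was purified from 500 ng of total RNA, libraries were made with a strand-specific kit, the median insert was 155 bp and 15 PCR cycles were used. The molecule field of the labels reads genomic DNA, while the extraction protocol describes RNA, and the values were treated as RNA. Per the labels, replicates 1 to 3 of each age are passage 3 cultures and replicates 4 to 6 passage 4 cultures. The library names carry 3 codes, taken here to be library pools, of which passage 3 takes 1. The names do not say what the codes stand for.

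The authors deposited a single table of raw counts per gene, 46078 genes by 12 libraries, with no normalization. Its values are whole numbers, and the deposited counts sum to between 37169188 and 51126670 per library. The column names show alignment by STAR, per the file headers. Per the submitters' processing notes, the tools were FastQC 0.11.8, cutadapt 2.5, Trim Galore 0.6.4, STAR, HISAT2 2.1.0, Picard, SAMtools 1.9, featureCounts 1.6.4, StringTie 2.0, deepTools 3.3.1, MultiQC 1.7 and DESeq2 1.28.1, with the GRCm38 build. The strand setting, annotation release and treatment of reads that map to several genes are not given in the sources used here, so genes with near-identical copies, such as defensins and glutathione transferases, are uncertain, as are overlapping and antisense genes. Counts were made without molecular identifiers, so PCR copies are not told apart.

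From the counts, edgeR 4.0.16 (R 4.3.3) was run with TMM factors, filterByExpr grouped by age (minimum count 10, minimum total 15) and the robust quasi-likelihood test. Of 26728 genes with a count in any library, 14820 were tested. The age effect was fitted with passage as a term, because passage is balanced over age and goes with the library pools. A model of 4 means, one per age and passage, gave the age effect within each passage and the difference between them. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. SE values were derived from the log2 fold change and the F statistic. CPM values and log2 CPM (prior count 2) used TMM-scaled library sizes. The values of genes near the floor of 3 counts cover counting error only.

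Before the data were examined, 33 gene lists were fixed, 20 of pathways and 13 of cell types. Lists with at least 5 tested genes entered camera (limma 3.58.1, preset correlation 0.01), camera with an estimated correlation, and fry. In all, 31 were tested. The fibroblast and smooth muscle list had 4 tested genes and was not tested, and the list of sex-linked genes served as a check. Y-linked Ddx3y lay between 35.9 and 51.9 CPM and Xist between 0.279 and 0.805 CPM over the 12 libraries.

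Named genes followed a rule fixed before the data were examined. The rule takes the 12 called genes with the largest change in each direction, with a mean of at least 1 CPM, a proper gene name and the same sign at both passages. Because 0 genes were called, its fallback applied, the 5 genes with the smallest p in each direction. It also takes up to 4 genes per list by smallest p, a fixed set of genes of antigen presentation, cell types and senescence, and 6 genes in each direction for passage. Genes from the passage 4 libraries alone were named by the first part without the same-sign condition, 12 in each direction, a set chosen after seeing the data. Some genes taken by the rule are not reported here. Members of lists that were called are named as examples beyond the rule after their values were seen. Coordinates come from GENCODE M21 on GRCm38, where 14762 of the 14820 tested genes were found by identifier.

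Replicates were compared before averaging. No pair of libraries of the same age and passage agreed within counting error alone. The labels share replicate numbers between ages. Within passage 4, the deviations of same-numbered libraries from their group means correlated at 0.18, 0.29 and 0.39. These values were not tested against chance, and some same-numbered libraries also share a pool. Whether the numbers pair the libraries there is therefore uncertain, and the labels do not say. The main fits leave the number out, and fits with it as a block are given beside them.

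The scripts were tested on simulated counts with 200 genes, picked at random, changed. Every simulated library followed its label. The shares below therefore do not describe genes at which real libraries lie with the other age. In the simulation of the 12-library age comparison on 14820 genes, 58.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 4.5% false calls. For passage 4 alone (15028 genes) the shares were 50.7%, 79.1% and 92.4%, with 9.2% false calls. The simulation of the 10 libraries (14871 genes) gave 82.1%, 88.1% and 98.5%, with 10.5% false calls, and that of the passage effect (14820 genes) 65.7%, 82.1% and 98.5%, with 6.8%. The false shares for passage 4 alone, for the 10 libraries and for the passage effect lay above the 5% aimed at, each in a single draw.

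Alternatives fixed before the data were examined were median-of-ratios size factors, no filter, a filter of 1 CPM in 6 libraries, DESeq2 1.42.0, no passage term, library pool in place of passage, the replicate number as a block, stricter thresholds, a test against a 1.5-fold change, leaving out each library, and leaving out mitochondrially encoded genes. Fits of each passage alone and of 10 libraries were added after seeing the data.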

Results

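Small intestinal organoids were grown from C57BL/6JRj mice of 2 ages and profiled by bulk RNA sequencing. Organoids are three-dimensional epithelial cultures that start from intestinal stem cells and contain stem, Paneth, goblet, enteroendocrine, tuft and absorptive cells without the surrounding tissue. The title of the study names the question, which is whether aged intestinal stem cells carry sources of inflammation within themselves through culture. Cultures came from Young mice (2 to 3 months, n = 6 libraries) and Aged mice (20 to 22 months, n = 6 libraries). Replicates 1 to 3 of each age were taken at passage 3, and replicates 4 to 6 at passage 4, after 4 to 5 weeks of culture. The labels do not say whether each replicate came from a separate mouse, so p-values measure the spread between these libraries, which may be partly technical. Total counts lay between 37169188 and 51126670 per library. At these depths 3 counts correspond to between 0.0587 and 0.0807 CPM (the count scaled to a library of 1e6), a limit that covers counting error only. Transcripts of the epithelium were abundant in all 12 libraries: Epcam lay between 1190 and 1420 CPM and Vil1 between 855 and 1010 CPM. The pan-leukocyte gene Ptprc reached at most 3 counts in any library, and the fibroblast collagen gene Col3a1 had 0 counts in all libraries, which allows at most 0.0807 CPM in the shallowest of them. Coro1a and Acta2 reached at most 7 and 4 counts. Other genes of the non-epithelial lists were not as low, with Vim between 8.7 and 13.7 CPM and Pecam1 and Laptm5 at up to 35 and 32 counts.

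Passage and age separated the libraries along different axes, with 2 exceptions. The first principal component of log2 CPM took 32.8% of the variance and placed all passage 3 libraries below 0 and all passage 4 libraries above 0. The second took 21.6% and separated the ages at passage 4, where Young libraries lay between -15.2 and -11.3 and Aged libraries between 16.1 and 19.2. At passage 3, Young replicate 3 scored 12.2, beside Aged replicates 2 and 3 at 14.1 and 17. Aged replicate 1 scored -20.6, beside Young replicates 1 and 2 at -18.4 and -17.7. The labels were used as given in every comparison, and counts without these 2 libraries are given beside the main ones.

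**Figure D1:**
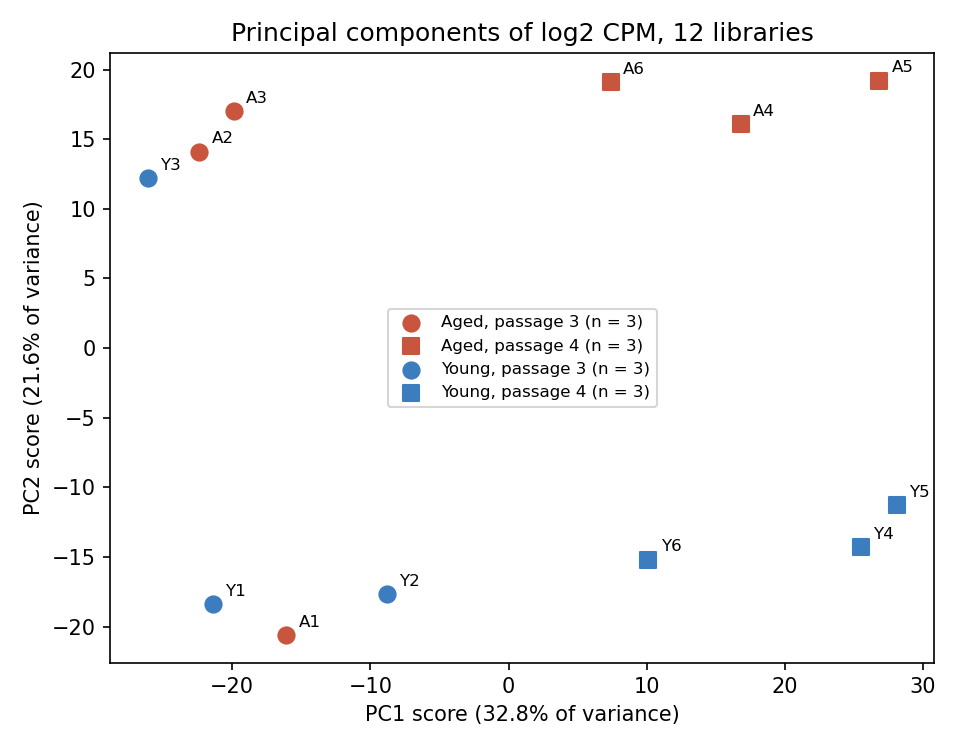
Scores of the 12 libraries on the first and second principal components of log2 CPM (axes in score units, with the percent of variance); blue marks Young, red Aged, circles passage 3 and squares passage 4, and each point carries its age initial and replicate number. Young replicate 3 (12.2 on the second component) lies with the Aged libraries and Aged replicate 1 (-20.6) with the Young ones.

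Across all 12 libraries, no single gene differed between Aged and Young organoids past the threshold. With passage as a term, edgeR's quasi-likelihood test called 0 of 14820 genes at a Benjamini-Hochberg adjusted p under 0.05, while 1283 genes had an unadjusted p under 0.05 and 741 would be expected by chance. The smallest adjusted p was 0.563, and DESeq2 called 3 genes. Among the genes with the smallest p that were higher in Aged organoids, none of which passed, were Xxylt1, a xylosyltransferase acting on Notch, Dnlz, a mitochondrial chaperone partner, the cytochrome P450 gene Cyp2c37 and the basement membrane collagen gene Col18a1. Xxylt1 (chromosome 16, 30955144 to 31081432, GRCm38) had 43.8 ± 3.6 CPM in Aged and 35.3 ± 2.43 CPM in Young organoids (SD, n = 6 each), a log2 difference of 0.32 ± 0.059 (SE). Cyp2c37 had a log2 difference of 0.96 ± 0.23 and Col18a1 of 0.73 ± 0.18. The genes with the smallest p in the other direction were Mpp7, Zfp292, Ubn2, Med13 and Ldhb, with log2 differences of -0.26, -0.23, -0.16, -0.19 and -0.74. Leaving out Aged replicate 1 gave 211 calls and leaving out Young replicate 3 gave 21, while leaving out any other single library gave 0.

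Within each passage, the 12-library model with 4 group means also called 0 genes by edgeR. At passage 3, 205 genes had an unadjusted p under 0.05, where 741 would be expected by chance, and DESeq2 called 0. At passage 4 there were 1349 genes with an unadjusted p under 0.05, against the same 741, and DESeq2 called 55. In that model the spread is shared between passages, so the wide spread among passage 3 libraries of one age enters the test at passage 4. The passage 4 libraries were therefore also fitted alone, a comparison chosen after seeing the data, as were the genes named from it.

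At passage 4 alone, Aged organoids (n = 3) differed from Young ones (n = 3) in genes of several functions. Higher in Aged cultures were Ly6e, a GPI-anchored surface protein induced by interferon, Itgam, an integrin chain best known from myeloid cells, the transcription factor gene Tfap2a, the calcium-activated potassium channel gene Kcnn4, the serine protease gene Prss32 and the acetylcholinesterase gene Ache. Lower in Aged cultures were the nucleoside transporter gene Slc28a2, the retinol dehydrogenase family gene Sdr16c5, the paternally expressed imprinted gene Peg3, the ubiquitin ligase gene Trim35, and Scg3, a protein of hormone secretory granules. Ly6e (chromosome 15, 74955051 to 74959905) measured 427 ± 51.9 CPM in Aged and 155 ± 30.8 CPM in Young organoids (SD), a log2 fold change of 1.47 ± 0.15 (SE) with an adjusted p of 0.00824. Itgam (chromosome 7, 128062640 to 128118491) measured 8.95 ± 0.681 against 3.25 ± 0.581 CPM, a log2 fold change of 1.47 ± 0.15 with an adjusted p of 0.00618. Trim35 (chromosome 14, 66297031 to 66311424) fell from 23.3 ± 4.51 CPM in Young to 6.02 ± 0.314 CPM in Aged organoids, a log2 fold change of -1.95 ± 0.14 with an adjusted p of 0.00181. Peg3 (chromosome 7, 6703892 to 6730431) measured 0.68 ± 0.196 CPM in Aged and 3.12 ± 0.544 CPM in Young organoids. All 4 are annotated as protein-coding, and the intervals span the whole gene.

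Among the 24 genes named from the passage 4 libraries, the largest log2 fold changes upwards were 2.55 for Tfap2a, 2.13 for Apoh, 1.98 for Prss32 and 1.68 for Kcnn4. Cnpy1 rose by 1.47 on the log2 scale, Upb1 by 1.4, Ache by 1.36, Parp3 by 1.26, Fam20a by 1.22 and Oit1 by 1.16. The largest downward were -3.08 for Slc28a2, -2.83 for Sdr16c5, -2.18 for Peg3 and -2.07 for Fam64a. Rims4 fell by 1.99, Mark1 by 1.77, Itpripl2 by 1.7, Scg3 by 1.53, Emid1 by 1.53, Lypd6 by 1.46 and Zfp711 by 1.46. In total, edgeR called 109 of 15028 genes at passage 4, 55 higher and 54 lower, of which 64 differed by at least 1 on the log2 scale. With the replicate number as a block, 795 genes were called, in a fit with fewer degrees of freedom and a pairing that the labels do not state. Leaving out one library at a time gave between 33 and 113 calls, with 37 without Young replicate 4, 33 without Aged replicate 4 and 59 without Young replicate 5. The passage 3 libraries fitted alone gave 0 calls by edgeR, with 165 genes at an unadjusted p under 0.05, where 742 would be expected by chance.

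**Figure D2:**
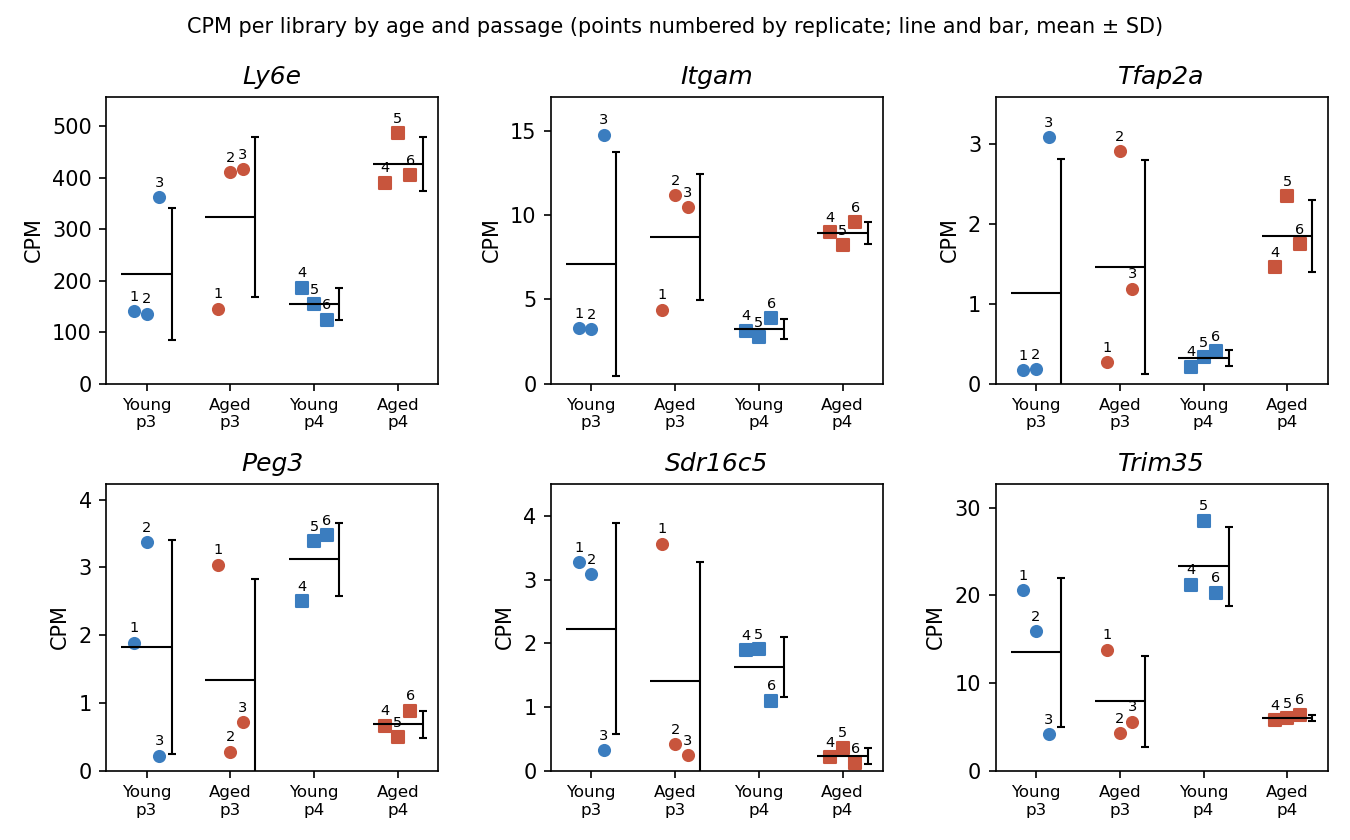
CPM of 6 genes in each library (vertical axis, linear, from 0), by age and passage (horizontal axis, p3 and p4 for passages 3 and 4); points are libraries numbered by replicate, lines are group means and bars SD (n = 3). At passage 4 the ages do not overlap for these genes, which were named because they passed there (10% of all genes would separate 3 from 3 by chance), and at passage 3 Young replicate 3 and Aged replicate 1 lie at the level of the other age.

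Without Young replicate 3 and Aged replicate 1, the remaining 10 libraries gave many calls between ages. This set was chosen because those libraries lay away from their own age, so its count is not independent evidence of an age effect. edgeR called 667 of 14871 genes, 413 higher and 254 lower in Aged organoids. Ly6e (log2 fold change 1.51 ± 0.099, adjusted p = 2.64e-05), Itgam (1.57 ± 0.1, adjusted p = 1.6e-05), Trim35 (-1.93 ± 0.12, adjusted p = 1.19e-05) and Slc28a2 (-3.02 ± 0.21, adjusted p = 1.98e-05) were among them. Within this set, 111 genes were called at passage 3 and 205 at passage 4.

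Several lists of genes fixed before the data were examined leaned to one age in the 12 libraries, without a member that passed, and only under an assumed low correlation between genes. By camera with a preset correlation of 0.01, 9 of 31 lists passed, 8 towards Aged and 1 towards Young organoids, while with a correlation estimated per list 0 passed (smallest adjusted p = 0.748) and fry called 0. Tuft cell markers were higher in Aged organoids at 21 of 23 tested genes (median log2 difference 0.33, adjusted p = 1.95e-06). Type I and III interferon-stimulated genes were higher at 33 of 35 (median 0.32, adjusted p = 3.16e-05), with values of 0.24 for Ifi27l2b, 0.21 for Ifi35 and 1.07 for Apol9b, none of which passed alone. Genes of oxidative stress and xenobiotic metabolism were higher at 30 of 43 (adjusted p = 5.05e-05), including the glutathione transferase genes Gstm1 (0.4), Gsta1 (0.49) and Gsta2 (0.51). The sequences of Gsta1 and Gsta2 are similar enough that reads can be split between these 2 genes. Markers of proximal enterocytes (25 of 30 positive, adjusted p = 0.000457), lipid absorption genes (21 of 24, adjusted p = 0.000723), distal enterocyte markers (17 of 21, adjusted p = 0.0014), goblet cell markers (19 of 22, adjusted p = 0.00623) and MHC class I genes (18 of 24, adjusted p = 0.00957) also leaned towards Aged organoids. Glycolysis and hypoxia genes were lower in Aged organoids at 28 of 28 tested genes (median -0.13, adjusted p = 1.1e-06), with -0.38 for the mitophagy gene Bnip3 and -0.14 for the hexokinase gene Hk2. Adjusted over the list alone, 1 tuft cell marker passed in the 12 libraries, and 0 genes passed in the other 8 lists. Young replicate 3 had a higher mean log2 CPM than Young replicates 1 and 2 for the tuft cell list (1.24 against 0.46 and 0.73) and the interferon list (3.43 against 2.48 and 1.51), and also for the glycolysis list (7.93 against 7.67 and 7.6). Aged replicate 1 lay below Aged replicates 2 and 3 for the tuft cell list (0.7 against 1.01 and 1.27) and the interferon list (2.46 against 2.88 and 2.83), but not for MHC class I genes (4.71 against 4.77 and 4.63).

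At passage 4 alone, 13 lists passed by camera, 11 up and 2 down, and 0 passed with an estimated correlation (smallest adjusted p = 0.246). Both came from a fit without the replicate number. Xenobiotic metabolism genes were higher at 33 of 43 (adjusted p = 1.32e-11), with Gstm1 (0.7 ± 0.076, adjusted p = 0.00624) and Gsta1 (0.71 ± 0.11, adjusted p = 0.0307) called, and 15 called when adjusted over the list alone. Proximal enterocyte markers were higher at 25 of 30 (adjusted p = 4.23e-11), lipid absorption genes at 22 of 24 (adjusted p = 2.35e-10) and interferon-stimulated genes at 34 of 35 (adjusted p = 2.02e-07), with adjusted p = 0.609 and 0.749 for the lipid and interferon lists when the correlation was estimated. The mean log2 CPM of the interferon list was 2.56, 2.15 and 3.57 in Aged and 2.09, 1.83 and 2.65 in Young replicates 4, 5 and 6, higher in Aged within each number, while Aged replicate 6 stood highest and the numbers differed among themselves. Enteroendocrine markers leaned lower at 19 of 28 (adjusted p = 0.00123), with 3 called: Scg3, the proglucagon gene Gcg (-0.84 ± 0.13, adjusted p = 0.0379) and Scg2 (-0.79). The immune cell list passed (adjusted p = 0.0023) on 6 tested genes, of which Itgam alone was called. In the 10 libraries, fry called 3 lists, which were the tuft cell, immune cell and distal enterocyte markers, and with an estimated correlation 0 lists passed (adjusted p = 0.228, 0.233 and 0.233 for these 3).

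Genes of antigen presentation, stem cells and senescence were examined in each case. H2-Ab1, an MHC class II chain, had a log2 difference of -0.99 ± 0.42 in the 12 libraries (adjusted p = 0.565), with 1.25 ± 0.982 CPM in Aged and 2.42 ± 0.617 CPM in Young organoids (SD, n = 6). In the 10 libraries its difference was -1.45 ± 0.32 (adjusted p = 0.0274), while Ctss of the same list was called in the other direction (0.31, edgeR adjusted p = 0.0483). The MHC class II list did not pass by camera in the 12 libraries (adjusted p = 0.847). Cd74, H2-Aa, Ciita and Cdkn2a lay below the count filter, with at most 7, 3, 13 and 12 counts in any library, so they were not tested in the main fit. Without a filter, edgeR called 0 genes for age in the 12 libraries. Differences for the stem cell receptor gene Lgr5 (-0.18 ± 0.077, adjusted p = 0.563), Olfm4 (-0.26 ± 0.5), the proliferation marker gene Mki67 (-0.01 ± 0.076), the cell cycle inhibitor gene Cdkn1a (-0.06 ± 0.12), B2m (0.12 ± 0.077) and Isg15 (0.5 ± 0.49) did not pass. Neither did those of Reg3g (-0.34 ± 0.1) and Reg3b (-0.7 ± 0.35), which encode antimicrobial lectins.

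Passage 4 organoids carried more stem and Paneth cell transcripts and fewer tuft cell and regenerative epithelium transcripts than passage 3 organoids, as seen in single genes. As lists, these passed by fry (adjusted p = 0.00913 for stem, 0.00975 for Paneth and for tuft cell, and 0.0177 for regenerative genes). None of them passed by camera with an estimated correlation (adjusted p = 0.396 for the stem, Paneth and tuft cell lists and 0.421 for the regenerative list). Olfm4, a marker of crypt base stem cells, rose from 60.7 ± 46.8 to 638 ± 406 CPM in Young and from 39 ± 8.99 to 681 ± 268 CPM in Aged organoids (SD, n = 3 each), a log2 fold change of 3.76 ± 0.56 (adjusted p = 0.00154). The stem cell transcription factor gene Ascl2 rose by 1.54 ± 0.25, the lysozyme gene Lyz1 of Paneth cells by 1.34 ± 0.22 and Lgr5 by 0.45 ± 0.077 on the log2 scale. Of the stem cell list, 17 of 24 tested genes were called higher and 1 lower, and of the Paneth cell list 15 of 17 were called higher, Defa21 by 3.38 ± 0.66. Replicate 6 stood apart from the other passage 4 libraries in these lists, with mean log2 CPM for the stem cell list of 6.27 in Young and 6.53 in Aged replicate 6 (between 6.89 and 7.01 in replicates 4 and 5, at most 6.23 at passage 3). For the Paneth cell list Young replicate 6 (4.01) lay below Young replicate 2 of passage 3 (4.18). Defensin genes are near-identical copies, so their single values are uncertain. Wnt and Notch target genes were called higher at 13 and lower at 2 of 26, among them Nkd1 (log2 fold change 3), Sp5 (2.03) and Axin2 (1.4). Of tuft cell markers, 15 of 23 were called lower, with the kinase gene Dclk1 at -1.19 ± 0.17. Of the fetal and regenerative list, 10 were called lower and 3 higher of 24, with Clu at -2.8 ± 0.28, Msln at -2.68 ± 0.38, Ly6a at -1.91 ± 0.25 and Anxa1 at -1.76. All 7 tested mitochondrially encoded genes were called lower, between mt-Nd6 (-0.51) and mt-Nd5 (-0.74), and 18 of 43 xenobiotic metabolism genes were called lower against 1 higher.

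The 12 genes named for passage were Pcdh8 (4.02), Olfm4, Defa21, Tnfrsf19 (3.24), Pla2g5 (3.21) and Snai2 (3.14) upwards, and the basement membrane collagen gene Col4a1 (-3.8 ± 0.34, adjusted p = 4.15e-05), Clu, Msln, Ano1 (-2.11), Ctrb1 (-2.06) and Syt8 (-2) downwards. In total, edgeR called 4091 of 14820 genes, 2054 higher and 2037 lower at passage 4, with age as a term. By camera, 17 of 31 lists passed, 5 up and 12 down, and fry called 17. With an estimated correlation 0 passed, the smallest adjusted p being 0.173 for the mitochondrially encoded genes. Passage 3 libraries came from 1 library pool and passage 4 libraries from other pools, so passage and pool cannot be told apart.

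**Figure D3:**
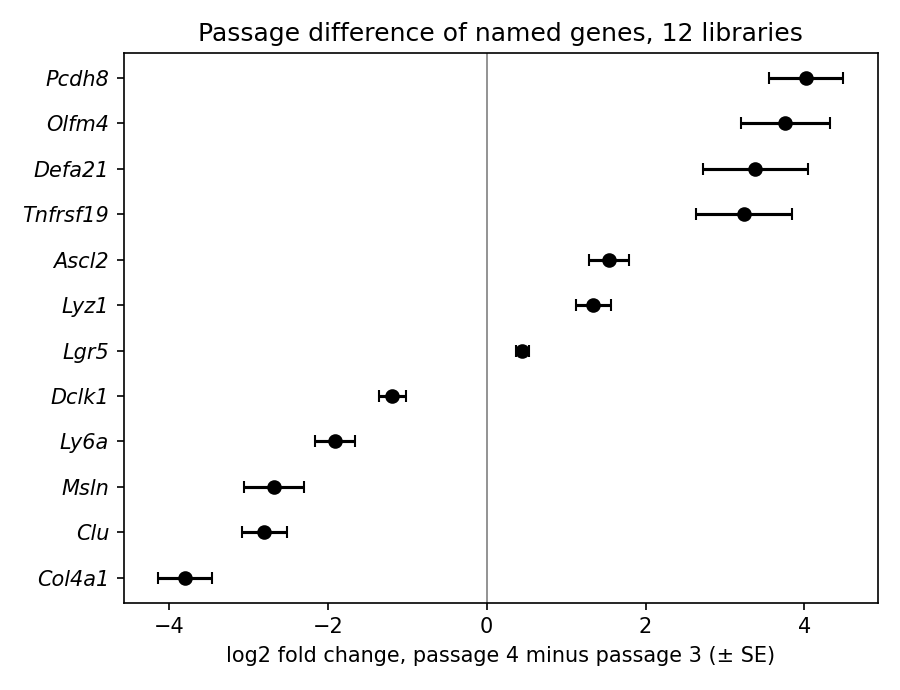
Log2 fold change, passage 4 minus passage 3 (horizontal axis, all 12 libraries, age as a term), of 12 genes named in the text; points are edgeR estimates and bars their SE. Pcdh8 (4.02) and Olfm4 (3.76) lie highest and Clu (-2.8) and Col4a1 (-3.8) lowest.

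The difference of the age effect between passages was tested itself. By edgeR, 0 of 14820 genes were called, and DESeq2 called 0. By edgeR, 288 genes had an unadjusted p under 0.05, where 741 would be expected by chance. With fewer small p-values than chance gives, the 0 calls do not show that the age effect is alike at both passages. Among the lists, 13 passed by camera with the preset correlation (10 up, 3 down), 0 with an estimated correlation (smallest adjusted p = 0.21) and 0 by fry. Lipid absorption genes had a more positive age difference at passage 4 at 24 of 24 tested genes (adjusted p = 2.9e-14, and adjusted p = 0.406 with an estimated correlation; 1 gene called when adjusted over the list alone), and interferon-stimulated genes at 33 of 35 (adjusted p = 0.000302, and adjusted p = 0.916 with an estimated correlation). At passage 3, where Young replicate 3 and Aged replicate 1 lie, interferon-stimulated genes had a median age difference of -0.04, against 0.74 at passage 4.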

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

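All tests of explanations in this part were chosen only after the results they bear on had been seen. A library standing far from the other 5 of its age was looked for in 190 groups of 6 values, after centring each passage, except for total counts and the signature of passage 4 genes. The gap to the nearest library, as a ratio of the range, passed the 5% critical value in 37 groups. Chance flags about 1 in 20, here 9.5, and the groups share libraries and genes. That share does not hold for the signature and the genes named from passage 4. Those genes were picked because the passage 4 libraries of each age lay close together and apart from the other age. Most of the 37 flags fall on them, so the excess over 9.5 decides nothing about chance.

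Young replicate 3 and Aged replicate 1 stood apart in nearly all of the flagged groups. On the mean over 108 genes called at passage 4, each signed by its direction there, Young replicate 3 lay at 0.68 and Aged replicate 1 at -0.7, with gap ratios of 0.917 and 0.983. The other passage 3 libraries lay at -0.61 and -0.67 (Young) and 0.73 and 0.71 (Aged). These genes were called without any passage 3 library. Young replicate 3 lay on the Aged side at 91.7% of them and Aged replicate 1 on the Aged side at 2.8%. The pair being exchanged between ages may account for this, since 91.7% was the lower of the shares lying with the other age. Depth is argued against, since Young replicate 3 and Aged replicate 1 lay 26.5 and 36.7 on the second principal component from the library of their age nearest in total count (0.775% and 2.07% apart in total), where the other libraries of those ages spanned 7.1 and 5.1. An equal mixture of RNA of both ages is argued against by the median position of the libraries, at least 96.7% of the way from the labelled age to the other. An exchange of cultures, RNA or labels cannot be separated here, and cultures that truly resemble the other age stay open and untested. No label was changed.

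Young replicate 3 had the highest value of its age for the immune cell list score (gap ratio 0.85) and for Cyp2c37 (0.72), Tfap2a (0.75), Apoh (0.652), Prss32 (0.823), Ly6e (0.65), Itgam (0.746), Upb1 (0.631), Ache (0.805) and Oit1 (0.753). It had the lowest for Slc28a2 (0.686), Sdr16c5 (0.757), Peg3 (0.747), Rims4 (0.696), Trim35 (0.79), Scg3 (0.7), Emid1 (0.805), Lypd6 (0.693) and Zfp711 (0.686). Aged replicate 1 had the lowest value of its age for Xxylt1 (0.845), Cyp2c37 (0.678), Col18a1 (0.683), Ly6e (0.805), Itgam (0.845), Upb1 (0.685), Ache (0.684), Parp3 (0.836), Fam20a (0.905) and Oit1 (0.841). It had the highest for Zfp292 (0.755), Slc28a2 (0.745), Sdr16c5 (0.648), Trim35 (0.773) and Emid1 (0.654). The one group with another library apart was Lyz1 in the Young libraries, where Young replicate 6 was lowest (0.644).

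The age effect differed between passages for 13 lists by camera with the preset correlation, with these adjusted p-values: 2.9e-14 for lipid absorption, 3.15e-11 for proximal and 3.07e-07 for distal enterocyte markers, 1.56e-07 for xenobiotic metabolism, 0.000226 for enteroendocrine markers, 0.000302 for type I and III interferon-stimulated genes, 0.00153 for fatty acid oxidation, 0.00182 for tuft cell markers, 0.0147 for Wnt and Notch targets, 0.0253 for glycolysis and hypoxia, and 0.0464 each for MHC class I, immediate early genes and Paneth cell markers. Of these lists 0 passed with an estimated correlation or by fry. The passage 3 values include Young replicate 3 and Aged replicate 1, and these list tests were not run without them. Among the other passage 3 libraries, interferon list scores (mean log2 CPM) were 2.48 and 1.51 in Young and 2.88 and 2.83 in Aged. Tuft cell scores were 0.46 and 0.73 against 1.01 and 1.27. Both lists were higher in Aged there too. Lipid absorption scores overlapped, at 7.42 and 7.22 against 7.47 and 7.39.

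At passage 4, 109 genes were called between ages when those libraries were fitted alone. The pools within passage 4 are argued against as the cause, since 95 of the 109 stayed called in the same direction with pool as a term. Linked variants acting on nearby genes at a few loci are argued against for the set as a whole, since there were 7 neighbouring pairs within 1 Mb where random draws had a median of 9 (permutation p = 0.85 over 10000 draws). Variants at single genes stay open. Carried-over immune cells as the source of Itgam are argued against, since the highest mean among Ptprc, Coro1a, Laptm5 and Cd52 in the Aged passage 4 libraries was 0.558 CPM while Itgam lay at 9.05, both on unscaled library totals (8.95 for Itgam with TMM scaling). Age stays open as the biological difference, and with 3 libraries per age so does any unrecorded difference between the cultures.

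Between passages, 4091 genes were called. Without mitochondrially encoded genes 4055 were called, so the calls do not depend on those genes being counted. They held between 2.42% and 4.55% of the counts per library. Leaving them out could therefore change little, and the count does not decide on a shift in composition. Neither the library pools nor the replicates can be told apart from passage, because each pool and each replicate number lies within 1 passage. Inside passage 4 the pools differed at 2 genes.

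Other splits of the same libraries were fitted in the same way. For the age effect in 12 libraries and for the difference between passages the real count was 0, which every split reaches by construction (100 of 100 for each), so the splits decide nothing about chance there. The highest other splits gave 111 and 44. For the passage effect, 1 of 100 splits gave as many as the real 4091, which was the real one, and the highest other gave 2670. No other split that was run reached the real count. Of 461 possible splits 100 were run, and they treat the libraries as independent, which the labels do not state. For the age effect in 10 libraries, 1 of 100 gave as many as the real 667, with a highest other of 274, but the 2 libraries had been left out because they lay with the other age, so the labelled split was favoured beforehand and this decides nothing about chance. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. At passage 4 alone the real count was 109 and the highest other 0 (1 of 10 gave as many). In the 4-mean model at passage 4 the real count was 0 and the highest other 0 (10 of 10). At passage 3 the real count was 0 in both models and 10 of 10 gave as many, with a highest other of 249 in the 4-mean model and 364 for those libraries alone. In both models that other split set Young replicates 1 and 2 with Aged replicate 1 against the rest, which points to a structure of the libraries that does not follow the labels.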

How the results depend on the processing

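The fits of passage 4 alone and of 10 libraries without Young replicate 3 and Aged replicate 1, with their alternatives, were chosen after seeing the data. In 12 libraries the count of genes called for age stayed at 0 with other size factors, with no filter or a stricter one, with pool or no term in place of passage, and without mitochondrial genes. DESeq2 gave 3, and leaving out both libraries gave 667. Leaving out single libraries gave 0 to 211. The age effect within passage 3 gave 111 with both left out and 0 to 0 over single libraries. Within passage 4, DESeq2 gave 55, leaving out both libraries 205, the passage 4 libraries alone 109, and leaving out single libraries 0 to 4. The difference between passages stayed at 0 under all alternatives run, and at 0 to 0 over single libraries. The passage effect ranged from 3548 without a filter to 4433 by DESeq2, and from 2996 to 4371 over single libraries. Lists called for age fell from 9 to 0 with an estimated correlation and to 0 by fry, and ranged from 7 to 14 over single libraries (14 without Young replicate 6).

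For passage 4 alone, 109 calls became 64 with an absolute log2 fold change of at least 1, 36 at an adjusted p under 0.01, 22 in the test against a 1.5-fold change, 271 without a filter, 61 with the stricter filter, 372 by DESeq2 and 166 with pool as a term, and 33 to 113 over single libraries. Its 13 lists became 0 with an estimated correlation and 0 by fry, and 9 to 16 over single libraries. For the 10 libraries, 667 calls became 145, 275 and 69 under the same 3 thresholds, 1127 by DESeq2 and 249 without the passage term, and 430 to 710 over single libraries (440 without Young replicate 2 and 430 without Young replicate 4). Its 13 lists became 0 with an estimated correlation and 3 by fry, and 11 to 15 over single libraries. Where a threshold or a left-out library lowers a count, fewer genes or libraries are the construction of the alternative. Otherwise the cause was not tested.

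With the replicate number as a block, the 12-library age count stayed at 0, that of passage 4 alone became 795 and that of the 10 libraries 1202, and 10, 15 and 13 lists were called. Over the 6 numbers the correlations of same-numbered libraries were 0.22, -0.21, 0.12, 0.18, 0.29 and 0.39, and 4 of 6 matched their own number best. At passage 3 the group means include Young replicate 3 and Aged replicate 1, which lay with the other age. The correlations there therefore cannot decide on a pairing, which stays uncertain. Of 3801 values of named genes for age under alternatives, 3700 stayed on their side of the threshold and 101 newly passed it. Of 302 values for passage 4 alone, 40 lost their call, and all 212 for passage kept theirs. No called gene changed sign, and 49 of 4315 values did so without a call on either side. Depth limits genes such as Cd74 and Ciita, with at most 7 and 13 counts.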

Other observations

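The test of imprinted genes in this part was chosen only after the genes called at passage 4 had been seen. Some single enteroendocrine and antimicrobial genes also differed between passages, without a theme that held in every list test. Neurog3, the transcription factor that starts enteroendocrine differentiation, was higher by 1.31 on the log2 scale (edgeR adjusted p = 0.000383), Pax4 by 1.01 and the somatostatin gene Sst by 0.71, with 6 of 28 enteroendocrine markers called higher and 0 lower. That list passed by camera with the preset correlation (adjusted p = 0.0417), but not with an estimated correlation (adjusted p = 0.587) or by fry (adjusted p = 0.0895). Among antimicrobial and barrier genes, Wfdc2 (-3.92), Reg3a (-1.47) and Reg3g (-0.69) fell while the Paneth cell genes Ang4 (1.05) and Itln1 (0.93) rose. Wfdc2 was not among the genes named for passage in spite of its large change, so it missed the threshold or the mean of 1 CPM. The antimicrobial and barrier list, with 4 genes called higher and 5 lower, did not pass by camera (adjusted p = 0.183) and passed by fry (adjusted p = 0.022). The stomach pepsinogen gene Pgc rose by 2.4. Pool, replicate and passage cannot be told apart for these genes either.

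Peg3 is an imprinted gene, expressed from the paternal copy, and its fall in Aged passage 4 organoids prompted a hypothesis that imprinted genes were called more often than others. A list of 70 imprinted genes was written from general knowledge after the called genes had been seen, so it is not independent of them, and it includes genes imprinted in other tissues. Without Peg3, 3 of 46 tested genes of the list were called, against 105 of 14981 other genes (6.52% and 0.701%, odds ratio 9.88, 95% interval 1.93 to 31.6, two-sided Fisher's exact p = 0.00438). In the 10 libraries, which include these 6 and so are no second test, the odds ratio without Peg3 was smaller, at 3.3 (95% interval 1.14 to 7.89). The called genes went both ways at passage 4, with Plagl1 at -0.89, Inpp5f at 0.52 and Slc22a18 at 0.34. The excess rests on few genes and genes are not independent, so imprinted genes may be over-represented, as a hypothesis for other cultures.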
